A study of Homo sapiens with 9 samples.

How the data were processed

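Total RNA of HepG2 cells was reverse transcribed from an oligo(dT) primer, labelled with biotin by in vitro transcription and hybridised to arrays, per the labels' protocols. The 9 arrays fall into 3 groups of 3, knockdown1, knockdown2 and control, each with replicate numbers 1, 2 and 3, all taken from the sample titles. The series' design text describes an siRNA double knockdown of HNF4alpha and HNF4gamma. The labels do not say how knockdown1 and knockdown2 differ or what the control received. They also do not say that replicates were separate cultures, so all p-values measure the spread between these arrays, which may be technical. No 2 arrays of a group shared more than 1.37% of their values exactly, and each was counted as 1 replicate.

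The deposited values are linear probe-set intensities made by the authors with MAS5, the Affymetrix signal algorithm, per the submitters' processing notes. The version of MAS5 is not given in the sources used here. The values themselves show the scaling, since the mean of each array after trimming 2% at each end was 100.0. No detection calls were used here. The unit is thus a relative brightness with no count or depth behind it, and the number of arrays sets the precision. MAS5 subtracts mismatch or background signal, so dim probe sets scatter strongly. Of the tested genes, 31.6% had a mean scaled signal under 50, and their fold changes are the least certain.

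The array medians of the deposited signals differed by 1.28 times, from 12.3 to 15.7. A rule set before the data were examined called for scaling when they differed by more than 1.2 times, so each array was multiplied by a factor (0.898 to 1.15) that brought its median to 14.1, the median over all probe sets and arrays. Values were then taken as log2(signal + 1.41), a pseudocount of 0.1 of that median. Every fold change is on this scale, which understates the change of dim genes. The values as deposited, without this scaling, were added as an alternative after seeing the data. The scaling moved the median of all tested genes between knockdown1 and knockdown2 from 0.08 to -0.03 on the log2 scale, and changes are given relative to the scaled median.

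Probe sets were named from the platform annotation used here. Of 54675 probe sets, 62 were control probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Symbols were checked through the gene identifiers against a RefSeq gene table and 0 needed an update. Probe sets with several genes or none were left out of the gene tests. A probe set was kept if its signal was above its array's median in at least 3 of the 9 arrays, which left 29651 probe sets. Each gene was represented by its probe set with the highest mean log2 value, and 13056 genes were tested. Of 55 named genes with further probe sets above the filter, 102 such probe sets were compared, 93 had the same sign and 9 the opposite sign, and none of the 9 passed the threshold. No probe set was paired with HNF4A alone, so the planned check of its level was not analysed here. No genome was used, and no coordinates are given.

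Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of adjusted p under 0.05. All 9 arrays entered 1 fit with 3 groups. The contrasts were the mean of both knockdowns against control, each knockdown against control, and knockdown1 against knockdown2. Gene lists were written before the data were examined, from textbook knowledge of hepatocytes, of growth and stress responses and of other cell types. They hold 725 genes in 29 lists, of which 647 were annotated and 550 tested. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists, and again with camera's estimated correlation and with fry. Overlap between the knockdowns was set beside 100 simulations without any change. Each drew all 9 arrays anew as independent noise around the genes' means, with a simulated control group shared by both comparisons.

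The genes named were chosen by a rule fixed before the data were examined. HNF4A and HNF4G came first. For both knockdowns against control, the rule took the 12 largest rises and the 12 largest falls among called genes whose 6 knockdown arrays all lay on the same side of the 3 controls. For each single knockdown it took the 4 largest each way, and between the knockdowns the 8 largest each way, among called genes whose arrays did not overlap. From each list it took the 3 called members with the largest change and up to 1 called member that moved against the majority. The rule gave 132 genes, and genes named outside it in the closing section are said to be so where they appear.

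The fit was tested on simulated data with the real genes' means and spreads and 67, 67 and 66 genes among 13056 changed 1.5-fold, 2-fold and 4-fold. For both knockdowns against control it recovered 61.2% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 90.9% of those changed 4-fold, and 8.28% of its calls were false. For knockdown1 against control these shares were 32.8%, 70.1%, 97.0% and 6.34%, for knockdown2 against control 29.9%, 79.1%, 90.9% and 6.34%, and between the knockdowns 37.3%, 73.1%, 93.9% and 4.90%. Far fewer genes were changed here than were called in the data (4256 over both knockdowns), and the adjustment depends on that share. The noise was independent and drawn once per comparison. These shares therefore do not give the recovery in the real comparisons.

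Alternatives were quantile normalization, centring on the tested genes, no pseudocount or a pseudocount equal to the median, no filter or a filter at the 75th percentile, the mean over a gene's probe sets, eBayes without a trend or with robust estimation, only the arrays compared, the replicate number as a block, all probe sets in place of genes, a threshold of 0.01, and leaving out each array in turn.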

Results

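Gene expression was measured with 9 oligonucleotide arrays in HepG2, a cell line derived from a human hepatocellular carcinoma that keeps many hepatocyte functions. The cells had received small interfering RNAs against HNF4alpha and HNF4gamma together, or a control. Both targets are nuclear receptors of the HNF4 family, and HNF4alpha is a main regulator of hepatocyte genes. The labels give 3 groups of 3 arrays, named knockdown1, knockdown2 and control, and do not say how knockdown1 and knockdown2 differ. Each array gives a linear signal for 54675 probe sets, and the array medians of the deposited signals differed by up to 1.28 times. After scaling to a common median of 14.1, log2 values of the 13056 tested genes, left after the filter on dim probe sets, were correlated between arrays. Arrays of the same group correlated at 0.973 to 0.978, and arrays of different groups at 0.931 to 0.953. Genes are not independent replicates, so these correlations describe the arrays only. The labels do not state that the arrays came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The number of arrays, 3 per group, limits the precision of every comparison.

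The first comparison checks the targeted genes. HNF4G, which encodes HNF4gamma, was lower over both knockdowns than in control. Its brighter probe set gave a scaled signal of 18.5 ± 4.66 (SD, n = 3) in knockdown1, 31.6 ± 9.14 (SD, n = 3) in knockdown2 and 46.0 ± 1.65 (SD, n = 3) in control. Over both knockdowns HNF4G fell by 0.92 on the log2 scale (SE 0.24, limma adjusted p = 0.0034), and all 6 knockdown arrays lay below all 3 control arrays. In knockdown1 alone it fell by 1.28 (SE 0.28, limma adjusted p = 5.38e-04). In knockdown2 alone the difference from control was -0.56 (SE 0.28, limma adjusted p = 0.141), and the 2 knockdowns differed by -0.72 (SE 0.28, limma adjusted p = 0.0517). A dimmer HNF4G probe set gave 6.33 ± 5.63 (SD, n = 3) in knockdown1, 5.72 ± 6.60 (SD, n = 3) in knockdown2 and 29.1 ± 8.11 (SD, n = 3) in control, a log2 fold change of -2.34 over both knockdowns (SE 0.63, limma adjusted p = 0.0087 over all probe sets). By that probe set HNF4G fell in knockdown1 (-2.20, SE 0.73, limma adjusted p = 0.0295) and in knockdown2 (-2.48, SE 0.73, limma adjusted p = 0.0173), and the difference between the knockdowns was 0.28 (SE 0.73, limma adjusted p = 0.839). These signals lie near the bottom of the measured range, so the size of the fall is uncertain. The level of HNF4A was not analysed here, because no probe set in the annotation used here is paired with that gene alone.

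**Figure D1:**
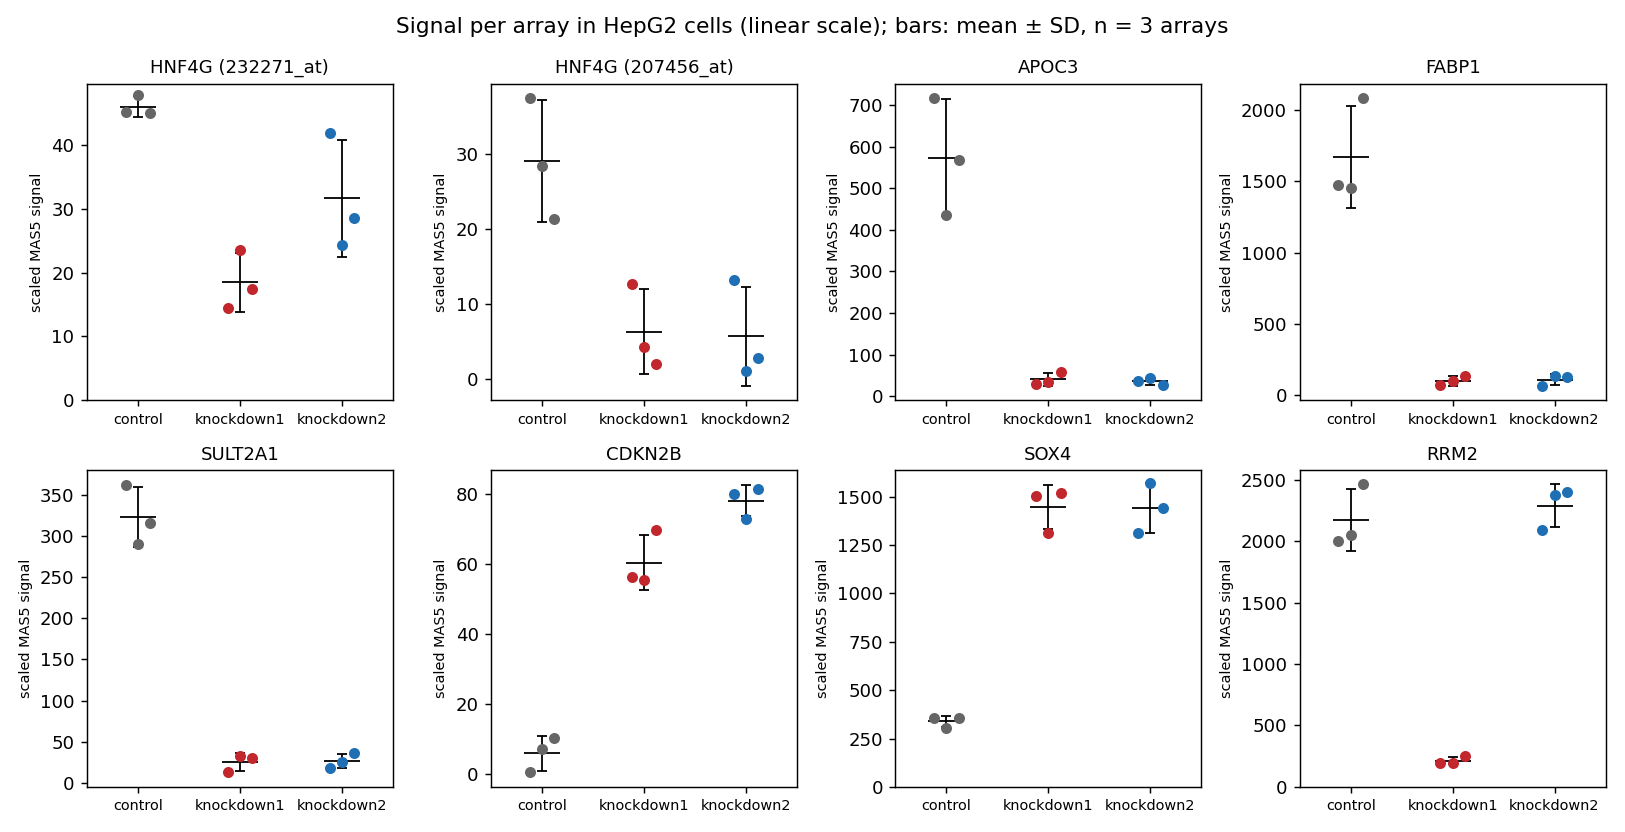
Scaled array signal on a linear axis for HNF4G (both probe sets) and 6 further genes in the 3 groups; each point is 1 array, and bars give the mean and SD of 3 arrays. APOC3, FABP1 and SULT2A1 lie far below control in both knockdowns, CDKN2B and SOX4 lie above control in both, and RRM2 lies at 214 in knockdown1 against 2290 in knockdown2 and 2172 in control.

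Taking both knockdowns against control, many genes of hepatocyte metabolism and some of secreted plasma proteins fell. List by list, with the tests, they are given further on, and no list passed with an estimated correlation (smallest adjusted p = 0.291). FABP1, the liver fatty acid binding protein, went from a signal of 1669 ± 358 (SD, n = 3) in control to 101 ± 33.7 in knockdown1 and 110 ± 37.5 in knockdown2, log2 fold changes of -4.06 (SE 0.22) and -3.94 (SE 0.22) in turn. Over both knockdowns its adjusted p was 8.58e-15. CIDEB, a lipid droplet protein of hepatocytes, fell by 4.10 (SE 0.15, adjusted p = 7.70e-17), and SOAT2, which esterifies cholesterol, fell by 3.61 (SE 0.22, adjusted p = 1.19e-12). The largest rises were those of the protease gene PRSS23 (3.95, SE 0.31, adjusted p = 1.12e-10), the protease inhibitor TFPI2 (3.84, SE 0.38, adjusted p = 5.78e-09) and CDKN2B (3.59, SE 0.35, adjusted p = 4.47e-09), which encodes the cyclin-dependent kinase inhibitor p15. Each of these 6 genes lay on the same side of all 3 control arrays in all 6 knockdown arrays. PRSS23, TFPI2 and CDKN2B lay near the bottom of the signal range in control (2.15, 6.14 and 6.01), so their fold changes and their ranks among the rises depend on the pseudocount.

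Other genes with large falls were CYP4F3 and CYP4F12, which encode fatty acid hydroxylases (log2 fold changes of -4.78, SE 0.20, and -3.57, SE 0.27), the apolipoprotein gene APOC3 (-3.87, SE 0.19), and SULT2A1, which sulfates bile acids and steroids (-3.62, SE 0.23). CYP19A1, the aromatase gene, fell by 3.75 on the log2 scale (SE 0.35) and SLC6A4, the serotonin transporter gene, fell by 3.55 (SE 0.16). UPK3A, UNC93A and ANKS4B also belonged to the 12 largest falls (-4.28, SE 0.61, -3.90, SE 0.41, and -3.47, SE 0.51), with knockdown signals below 9 on arrays whose common median was 14.1. The further large rises included PAQR5 (3.32, SE 0.16), NES, which encodes the intermediate filament protein nestin (3.24, SE 0.15), the growth-response transcription factor gene EGR3 (2.98, SE 0.17), SYTL2 (2.95, SE 0.24), HIC1 (2.92, SE 0.36), THSD7A (2.80, SE 0.40), the keratin gene KRT12 (2.67, SE 0.32) and the non-coding gene HECW2-AS1 (3.05, SE 0.20). CXCL8, which encodes interleukin-8, rose by 2.72 (SE 0.22). The adjusted p-values of these genes ran from 7.12e-16 for CYP4F3 to 4.22e-06 for ANKS4B. The control signals of HIC1, THSD7A, KRT12, SYTL2, HECW2-AS1 and CXCL8 and the knockdown signals of CYP4F3 lay below the common median, so their fold changes depend on the pseudocount. For HIC1 the value was 3.48 without a pseudocount and 1.40 with a pseudocount equal to the median. The probe sets of the CYP4F genes and of CXCL8 may pick up related transcripts, so their values are uncertain to that extent.

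By limma with Benjamini-Hochberg adjustment, 4256 of 13056 tested genes changed, 1916 higher and 2340 lower, and 1064 of them changed at least 2-fold (409 higher and 655 lower). In 20.9% of the tested genes the 6 knockdown arrays did not overlap with the 3 control arrays, against 2.38% by chance. Leaving out control replicate 3 turned the balance to 2575 higher and 1853 lower, and leaving out control replicate 2 gave 1468 higher and 2787 lower. Their scaling factors were 1.15 and 0.904 in turn, and whether the scaling caused these turns was not tested. Other scalings called more genes, 5496 with the values as deposited, 5560 after quantile normalization and 5332 with each array centred on the tested genes. With the 6 knockdown arrays pooled as 1 group, so that differences between the knockdowns count as spread, 2205 genes passed.

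Of 29 gene lists fixed beforehand, 17 were shifted as a group in the camera test with a preset inter-gene correlation of 0.01, 16 down and 1 up. None of the 17 passed when camera estimated the correlation of each list from the arrays. The smallest adjusted p was then 0.291, and the 29 unadjusted values reached down to 0.0261. With fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes, 18 lists moved down and 3 up. In the paragraphs that follow, counts of genes that rose or fell refer to adjustment over all 13056 genes. Adjusted over the list alone the counts were the same, except for the 7 lists where both are given. Values over both knockdowns can average unlike groups. Of 116 named genes other than the 16 chosen for it, 51 differed between the knockdowns, 27 lower and 24 higher in knockdown1.

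**Figure D2:**
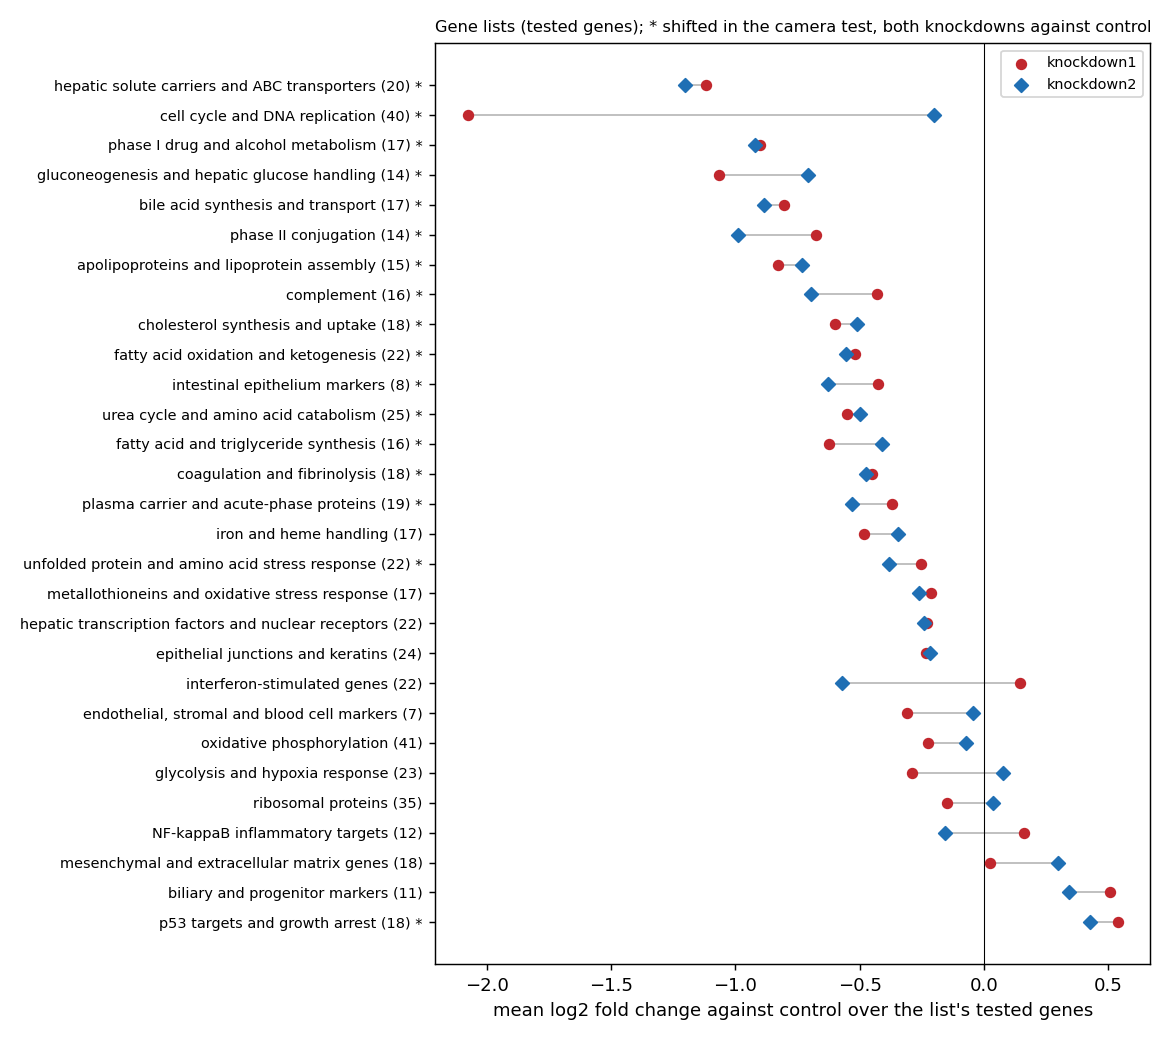
Mean log2 fold change against control of each gene list in knockdown1 (circles) and knockdown2 (diamonds), with the number of tested genes in brackets and an asterisk for the 17 lists shifted over both knockdowns. Most hepatic lists lie to the left of 0 at similar places in both knockdowns, whereas the cell cycle list lies at -2.08 in knockdown1 and -0.20 in knockdown2.

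In the apolipoprotein and lipoprotein assembly list, 8 of 15 tested genes fell and 1 rose (camera adjusted p = 1.17e-04, adjusted p = 0.433 with an estimated correlation). Besides APOC3, the falls included MTTP, which loads lipid onto nascent lipoproteins (-2.07, SE 0.15, adjusted p = 1.95e-11), and LCAT, which esterifies cholesterol in plasma (-1.29, SE 0.17, adjusted p = 5.92e-07), while CETP, the cholesteryl ester transfer protein gene, rose (0.98, SE 0.23, adjusted p = 0.0011). In the fatty acid oxidation and ketogenesis list, 12 of 22 genes fell and 1 rose (camera adjusted p = 0.0022, adjusted p = 0.476 with an estimated correlation). BDH1, an enzyme of ketone body metabolism, fell (-1.78, SE 0.19, adjusted p = 1.87e-08) and ACSL1, an acyl-CoA synthetase gene, rose (1.24, SE 0.14, adjusted p = 6.19e-08). In the cholesterol synthesis and uptake list, 12 of 18 genes fell and 0 rose (camera adjusted p = 3.19e-06, adjusted p = 0.395 with an estimated correlation), among them ACAT2 (-1.17, SE 0.11) and NSDHL (-0.93, SE 0.12). In the fatty acid and triglyceride synthesis list, 9 of 16 genes fell and 0 rose (camera adjusted p = 0.0026, adjusted p = 0.395 with an estimated correlation). Both DGAT1 and DGAT2, which catalyse the last step of triglyceride synthesis, fell (-1.24, SE 0.15, and -1.12, SE 0.13).

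In the coagulation and fibrinolysis list, 8 of 18 tested genes fell and 0 rose (camera adjusted p = 0.0066, adjusted p = 0.476 with an estimated correlation). SERPINC1, which encodes antithrombin, went from 892 ± 129 (SD, n = 3) in control to 215 ± 40.5 and 208 ± 9.74 in knockdown1 and knockdown2 (-2.07, SE 0.14, adjusted p = 3.94e-12), and the coagulation factor VII gene F7 fell by 1.31 (SE 0.22, adjusted p = 2.27e-05). In the complement list, 7 of 16 genes fell and 1 rose (camera adjusted p = 0.013, adjusted p = 0.476 with an estimated correlation). C8B, C8A and CFB fell (-2.21, SE 0.35, -1.83, SE 0.40, and -1.24, SE 0.14). With a stricter filter on dim probe sets the complement list no longer passed (adjusted p = 0.12). In the plasma carrier and acute-phase list, 8 of 19 genes fell and 1 rose (camera adjusted p = 0.0027, adjusted p = 0.553 with an estimated correlation). The haptoglobin gene HP fell by 2.80 (SE 0.20, adjusted p = 1.85e-11), although its probe set may also pick up the related HPR, and ORM1 fell by 1.19 (SE 0.12, adjusted p = 9.19e-09), while the hemopexin gene HPX rose (0.72, SE 0.14, adjusted p = 1.27e-04).

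In the phase I drug and alcohol metabolism list, 10 of 17 tested genes fell and 1 rose (camera adjusted p = 0.0011, adjusted p = 0.291 with an estimated correlation). The list holds the CYP4F genes named above, and CYP4F2 also fell (-2.69, SE 0.51). The 1 gene that rose was CYP3A5 (1.13, SE 0.22, adjusted p = 2.32e-04), whose level was 81.3 ± 1.06 (SD, n = 3) in knockdown2 and 29.1 ± 9.05 in knockdown1, and whose call ended when the knockdown arrays were pooled (adjusted p = 0.0991). In the phase II conjugation list, 8 of 14 genes fell and 0 rose (camera adjusted p = 2.83e-04, adjusted p = 0.395 with an estimated correlation), with SULT2A1 first and the glutathione transferase genes GSTM4 and GSTM1 next (-1.81, SE 0.16, and -1.40, SE 0.15), which are near-identical family members and may share signal. In the bile acid synthesis and transport list, 12 of 17 genes fell and 0 rose (camera adjusted p = 6.23e-07, adjusted p = 0.300 with an estimated correlation). ACOX2 and SLC27A2, which act in bile acid synthesis, fell (-1.90, SE 0.14, and -1.65, SE 0.15), as did AKR1D1. In the hepatic solute carrier and ABC transporter list, 13 of 20 genes fell and 1 rose, and 16 fell and 1 rose adjusted over the list alone (camera adjusted p = 7.69e-08, adjusted p = 0.291 with an estimated correlation). The organic anion transporter gene SLCO2B1 and the citrate transporter gene SLC13A5 fell (-3.28, SE 0.23, and -3.08, SE 0.15), and SLC40A1, which encodes the iron exporter ferroportin, rose (0.88, SE 0.14, adjusted p = 8.50e-06).

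In the urea cycle and amino acid catabolism list, 14 of 25 tested genes fell and 3 rose (camera adjusted p = 0.0011, adjusted p = 0.476 with an estimated correlation). MAT1A, which makes S-adenosylmethionine in liver, went from 1303 ± 260 (SD, n = 3) in control to 454 ± 81.2 in knockdown1 and 269 ± 37.8 in knockdown2 (-1.89, SE 0.14, adjusted p = 3.29e-11), and HAAO and AGXT fell too (-1.66, SE 0.23, and -1.62, SE 0.22). In the gluconeogenesis and hepatic glucose handling list, 11 of 14 genes fell and 2 rose (camera adjusted p = 1.50e-05, adjusted p = 0.291 with an estimated correlation). PPARGC1A, a coactivator gene of the fasting response, fell by 1.67 (SE 0.17, adjusted p = 8.21e-09; -2.47 in knockdown1 and -0.87 in knockdown2), and the ketohexokinase gene KHK fell by 1.60 (SE 0.17, adjusted p = 3.22e-08). The gluconeogenic gene FBP1 fell by 1.60 (SE 0.52, adjusted p = 0.0176), a call that ended without control replicate 1 (adjusted p = 0.0875) or control replicate 2 (adjusted p = 0.0941). G6PC1, which encodes glucose-6-phosphatase, rose by 1.16 (SE 0.38, adjusted p = 0.0186), and its call ended without control replicate 1, where its value was 0.55 (adjusted p = 0.253). G6PC1 also missed the threshold without the filter, without the variance trend and with the knockdown arrays pooled (adjusted p = 0.065, 0.0672 and 0.077).

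The cell cycle and DNA replication list fell in all 40 of its tested genes (camera adjusted p = 7.02e-28, adjusted p = 0.291 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell by 2.01 (SE 0.12, adjusted p = 1.40e-12), KIF20A, a mitotic kinesin gene, by 1.83 (SE 0.14, adjusted p = 3.60e-11), and the proliferation marker MKI67 by 1.74 (SE 0.15, adjusted p = 4.76e-10). These averages joined unlike groups, since the list mean was -2.08 in knockdown1 and -0.20 in knockdown2, and the call of MCM5 ended when the knockdown arrays were pooled (adjusted p = 0.0857). In the p53 target and growth arrest list, 11 of 18 genes rose and 1 fell, and 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 9.54e-05, adjusted p = 0.476 with an estimated correlation). ZMAT3, PLK3 and CDKN1A, which encodes the cell cycle inhibitor p21, rose (1.80, SE 0.15, 1.25, SE 0.15, and 1.00, SE 0.12). ZMAT3 rose by 2.89 (SE 0.17) in knockdown1 and by 0.72 (SE 0.17) in knockdown2. A dimmer PLK3 probe set gave -0.24 (SE 0.26). The 1 gene that fell, MDM2, whose product degrades p53, gave -0.57 (SE 0.14, adjusted p = 0.0018), while of its 6 other probe sets 4 had the same sign and 2 gave 0.15 (SE 0.27) and 0.51 (SE 0.25). Its mean over the probe sets missed the threshold (adjusted p = 0.0621), as did the pooled fit (adjusted p = 0.0518).

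In the list of the unfolded protein and amino acid stress response, 9 of 22 tested genes fell and 1 rose (camera adjusted p = 0.0098, adjusted p = 0.686 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, and the lipoprotein receptor gene VLDLR fell (-1.72, SE 0.13, and -1.44, SE 0.14), and the pseudokinase gene TRIB3 rose (0.70, SE 0.13). Among intestinal epithelium markers, 3 of 8 tested genes fell and 0 rose (camera adjusted p = 0.0308, adjusted p = 0.395 with an estimated correlation). These were the microvillus protein gene VIL1 and the peptidase genes ANPEP and DPP4 (-1.88, SE 0.14, -1.11, SE 0.13, and -0.89, SE 0.12), which liver cells also express. The intestinal list no longer passed without the filter on dim probe sets (adjusted p = 0.142) or without control replicate 2 (adjusted p = 0.0895).

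The other 12 lists did not pass the camera test, although single members moved. With fry, 4 of them passed, iron and heme (down, adjusted p = 0.0423), metallothionein and oxidative stress (down, adjusted p = 0.0423), mesenchymal and extracellular matrix (up, adjusted p = 0.0436) and biliary and progenitor markers (up, adjusted p = 0.018). In the list of hepatic transcription factors and nuclear receptors (camera adjusted p = 0.192), 9 of 22 tested genes fell and 4 rose. PROX1 and FOXA3 rose (1.19, SE 0.13, and 0.87, SE 0.12) and NR5A2 fell (-0.94, SE 0.14). In the iron and heme list (camera adjusted p = 0.132), 7 of 17 genes fell and 3 rose, and 8 fell and 3 rose adjusted over the list alone. The hepcidin gene HAMP went from 503 ± 232 (SD, n = 3) in control to 43.4 ± 9.68 in knockdown1 and 89.4 ± 9.59 in knockdown2 (-2.90, SE 0.19, adjusted p = 2.84e-12). In the metallothionein and oxidative stress list (camera adjusted p = 0.196), 6 of 17 genes fell and 2 rose, and 6 fell and 3 rose adjusted over the list alone, with AKR1B10 lower (-1.82, SE 0.11) and GCLC higher (0.71, SE 0.10). In the epithelial junction and keratin list (camera adjusted p = 0.271), 7 of 24 genes fell and 3 rose. CDH1, which encodes E-cadherin, fell by 2.25 (SE 0.20, adjusted p = 9.69e-10), and KRT19, a keratin of bile duct cells, rose by 2.27 (SE 0.14, adjusted p = 1.40e-12). In the mesenchymal and extracellular matrix list (camera adjusted p = 0.133), 5 of 18 genes rose and 2 fell, with THBS1 and S100A4 higher (2.18, SE 0.17, and 1.70, SE 0.17, the latter 0.68 in knockdown1 and 2.71 in knockdown2) and LOX lower (-3.07, SE 0.13).

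In the biliary and progenitor marker list (camera adjusted p = 0.0887), 4 of 11 tested genes rose and 2 fell, and 4 rose and 3 fell adjusted over the list alone. SOX4, a transcription factor gene of progenitor cells, rose by 2.09 (SE 0.12, adjusted p = 2.19e-13), and CD24 rose by 1.55 (SE 0.21, adjusted p = 1.05e-06) on a probe set that may pick up related transcripts. The median of this list was -0.08 and its mean 0.42. In the interferon-stimulated list (camera adjusted p = 0.260), 7 of 22 genes fell and 1 rose, and 8 fell and 1 rose adjusted over the list alone, with XAF1 and IFI35 lower (-1.90, SE 0.33, and -1.17, SE 0.14). In the NF-kappaB inflammatory target list (camera adjusted p = 0.841), 3 of 12 genes fell and 1 rose. The chemokine gene CCL20 fell by 3.00 (SE 0.33) and CXCL8 rose, and the list's median of -0.05, its mean of 0.00 and the downward sign of the test differed. In the glycolysis and hypoxia list (camera adjusted p = 0.462), 6 of 23 genes fell and 4 rose, with P4HA1 lower (-1.03, SE 0.12, from -0.53 in knockdown1 and -1.53 in knockdown2). In the oxidative phosphorylation list (camera adjusted p = 0.0594), 7 of 41 genes fell and 0 rose, and 6 fell adjusted over the list alone, with NDUFB10 at -0.71 (SE 0.13, adjusted p = 1.04e-04). None of the 35 tested ribosomal protein genes passed the test (camera adjusted p = 0.493). Among endothelial, stromal and blood cell markers (camera adjusted p = 0.615), 2 of 7 genes rose and 1 fell, with a median of 0.01, a mean of -0.18 and an upward sign of the test. Of those 3 genes, CD14 fell with signals under 5 in both knockdowns, and PECAM1 and HBB rose, but other probe sets of PECAM1 and HBB gave values of the opposite sign that did not pass. The call of CD14 ended without control replicate 1 (adjusted p = 0.109) or control replicate 2 (adjusted p = 0.0507), and that of PECAM1 with the mean over its probe sets (adjusted p = 0.941). The call of HBB ended without control replicate 1 (0.44, adjusted p = 0.327) or knockdown1 replicate 3 (1.00, adjusted p = 0.0616), and under 5 other settings, with adjusted p from 0.0633 to 0.274.

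In knockdown1 against control, the largest falls after CYP4F3 (-4.83, SE 0.24, adjusted p = 1.04e-14) were those of CRYAA, an alpha-crystallin gene (-4.40, SE 0.41, adjusted p = 1.49e-09), CIDEB (-4.36, SE 0.18, adjusted p = 5.93e-16) and CYP4F12 (-4.23, SE 0.31, adjusted p = 2.00e-11). The largest rises were those of CXCL8 (4.35, SE 0.26, adjusted p = 3.44e-13), SYTL2 (3.90, SE 0.28, adjusted p = 9.06e-12), HECW2-AS1 (3.80, SE 0.23, adjusted p = 5.86e-13) and CDKN2B (3.41, SE 0.40, adjusted p = 1.18e-07). The knockdown1 signals of CRYAA (1.82) and CYP4F3 and the control signals of these 4 risen genes lay below the common median, so the sizes and ranks of those changes depend on the pseudocount. All 40 tested genes of the cell cycle list fell, and 11 of 14 genes of the glucose handling list fell. In total 4351 of 13056 genes changed, 1866 higher and 2485 lower, and 1466 changed at least 2-fold (490 higher and 976 lower). Arrays of the 2 groups did not overlap in 39.8% of the tested genes, against 10% by chance. The share of higher genes among those called, 42.9%, depended on the scaling of the arrays. It was 54.2% (3105 higher and 2628 lower) with the values as deposited, 53.7% (3107 higher and 2682 lower) after quantile normalization and 51.7% (2849 higher and 2664 lower) with each array centred on the tested genes. It also depended on single arrays, with 2488 higher and 2125 lower without control replicate 3 and 1499 higher and 2959 lower without control replicate 2.

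In knockdown2 against control, CYP4F3 (-4.72, SE 0.24, adjusted p = 2.14e-14), CYP19A1 (-4.49, SE 0.40, adjusted p = 1.20e-09), UNC93A (-4.40, SE 0.48, adjusted p = 4.46e-08) and UPK3A (-4.35, SE 0.70, adjusted p = 2.29e-05) fell the most. PRSS23 (4.98, SE 0.36, adjusted p = 3.11e-11), TFPI2 (4.48, SE 0.44, adjusted p = 6.71e-09), the transcriptional repressor gene RIPPLY3 (3.87, SE 0.21, adjusted p = 1.36e-13) and NES (3.79, SE 0.18, adjusted p = 7.99e-15) rose the most. The knockdown2 signals of these 4 falls and the control signals of PRSS23 and TFPI2 lay below the common median, so the sizes and ranks of those changes depend on the pseudocount. Of the 40 cell cycle genes, 10 fell and 2 rose. In total 3608 of 13056 genes changed, 1795 higher and 1813 lower, and 1057 changed at least 2-fold (459 higher and 598 lower). The balance depended on single control arrays, with 2522 higher and 1515 lower without control replicate 3 and 1416 higher and 2243 lower without control replicate 2. Arrays of the 2 groups did not overlap in 39.7% of the tested genes, against 10% by chance.

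**Figure D3:**
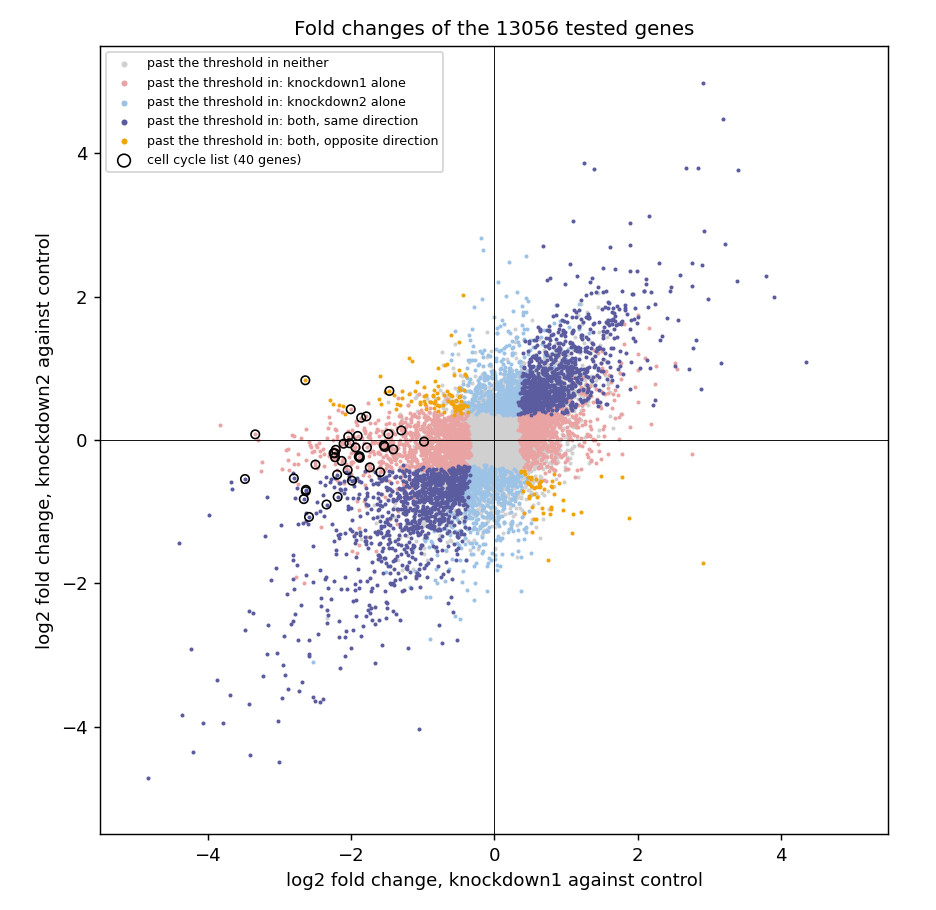
Log2 fold change against control in knockdown1 (horizontal axis) and knockdown2 (vertical axis) for each of the 13056 tested genes, coloured by the comparisons in which the gene passed adjusted p under 0.05. The 40 circled cell cycle genes all lie to the left of 0 and mostly near 0 on the vertical axis, off the diagonal along which many of the 2048 genes called in both knockdowns with the same sign lie.

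Both knockdowns moved many genes the same way. Of 2194 genes called in both comparisons, 2048 had the same sign, 969 higher and 1079 lower in both, and 146 had opposite signs. Independent lists of these sizes would share 257 higher and 345 lower genes. In 100 simulations without any change, with a simulated control group shared by both comparisons, 0 genes were called in both with the same sign. With no gene changed, the adjustment leaves few or no calls in either comparison. That 0 therefore cannot show how far shared controls add to the overlap of the real lists. Across genes the log2 fold changes correlated at r = 0.61, where sharing a simulated control group alone gave 0.50 on average. The simulated arrays held independent noise and none of the array-wide deviations of the real controls. Genes are not independent replicates. In the data 69.4% of the tested genes had the same sign against 66.7% simulated. For unchanged genes, the simulated 0.50 and 66.7% follow from equal groups sharing 1 control, whatever the noise. They therefore cannot show how much of the real agreement came from the shared controls. The covariance was 0.28 against 0.04 simulated, a difference of 0.24. The 3 control arrays cannot be divided into 2 groups of at least 2, so part of the excess may come from the shared controls. Of the 2048 genes, 1495 did not pass the test of a difference between the knockdowns, which does not show that they moved equally.

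Direct comparison of the knockdowns separated cell cycle genes and interferon-stimulated genes. All 40 cell cycle genes were lower in knockdown1 than in knockdown2, with a mean log2 difference of -1.88 (camera adjusted p = 1.73e-48, adjusted p = 0.235 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, gave a signal of 214 ± 29.6 (SD, n = 3) in knockdown1, 2290 ± 172 in knockdown2 and 2172 ± 253 in control, a difference of -3.41 between the knockdowns (SE 0.14, adjusted p = 9.66e-16). The S-phase cyclin gene CCNE2 (-3.47, SE 0.18, adjusted p = 9.67e-14), the midzone protein gene PRC1 (-3.29, SE 0.15, adjusted p = 4.57e-15) and the kinesin gene KIFC1 (-3.08, SE 0.20, adjusted p = 4.42e-12) were also lower in knockdown1 than in knockdown2. Against control, CCNE2 was higher in knockdown2 (0.83, SE 0.18, adjusted p = 7.59e-04) and KIFC1 was lower there (-0.59, SE 0.20, adjusted p = 0.0295). Of 22 interferon-stimulated genes, 11 were higher in knockdown1 than in knockdown2 and 0 lower, with a mean difference of 0.72 (camera adjusted p = 2.88e-05, adjusted p = 0.966 with an estimated correlation). In knockdown1 5 of these genes rose and 4 fell against control, and in knockdown2 8 fell and 0 rose.

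The third list to differ was that of glycolysis and hypoxia genes, with a mean difference of -0.37 (camera adjusted p = 0.0306, adjusted p = 0.966 with an estimated correlation), 8 genes lower and 2 higher in knockdown1. That call ended with the values as deposited (adjusted p = 0.0563), with quantile normalization (adjusted p = 0.0736), with the stricter filter (adjusted p = 0.174), with fry (adjusted p = 0.061), and without knockdown1 replicate 2 (adjusted p = 0.0736) or knockdown2 replicate 3 (adjusted p = 0.0555). Further genes much higher in knockdown1 than in knockdown2 were ANGPTL8, which encodes a hepatokine (4.63, SE 0.30, adjusted p = 3.13e-12), CXCL8 (3.26, SE 0.26, adjusted p = 1.21e-10), the Wnt antagonist gene DKK4 (2.99, SE 0.40, adjusted p = 1.51e-06) and IFIT1 (2.96, SE 0.25, adjusted p = 4.87e-10). ANGPTL8 rose in knockdown1 (2.92, SE 0.30) and fell in knockdown2 (-1.71, SE 0.30). DKK4 fell against control in both, by less in knockdown1 (-1.04, SE 0.40) than in knockdown2 (-4.03, SE 0.40). ZNF367 was much lower in knockdown1 (-4.04, SE 0.34, adjusted p = 3.83e-10). The lower group of ANGPTL8, DKK4, ZNF367 and KIFC1 lay below the common median, so the sizes of these differences depend on the pseudocount. In total 3473 of 13056 genes differed, 1368 higher and 2105 lower in knockdown1, and 1006 differed at least 2-fold (331 higher and 675 lower). The share of higher genes among these was 39.4%, and 57.1% (2803 higher and 2104 lower) with the values as deposited, 56.1% (2761 higher and 2158 lower) after quantile normalization and 52.0% (2410 higher and 2223 lower) with centred arrays. Without knockdown1 replicate 3 it was 29.5% (965 higher and 2303 lower). Arrays of the 2 groups did not overlap in 43.7% of the tested genes, against 10% by chance.

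**Figure D4:**
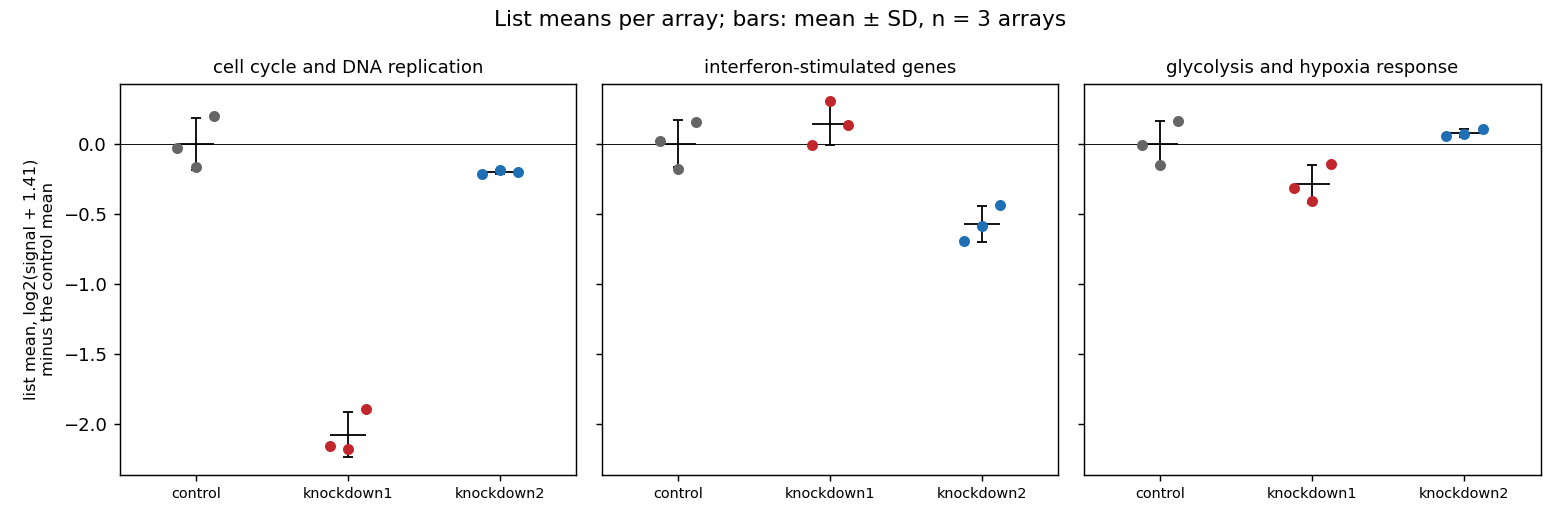
Mean over each list of log2(signal + 1.41) minus the control mean, for the 3 lists that differed between the knockdowns in the camera test with the preset correlation, none with an estimated correlation; each point is 1 array, and bars give the mean and SD of 3 arrays. The 3 knockdown1 arrays lie between -2.18 and -1.89 for the cell cycle list, and the 3 knockdown2 arrays between -0.22 and -0.18.

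As a measure of RNA quality, the log2 ratio of the 3 prime to the 5 prime control probe set of GAPDH was -0.12 ± 0.05 (SD, n = 3) in knockdown1, -0.11 ± 0.02 in knockdown2 and -0.12 ± 0.02 in control. For ACTB it was 0.30 ± 0.05 (SD, n = 3), 0.24 ± 0.03 and 0.31 ± 0.14. The differences between the groups were within the spread between arrays. For ACTB in control that spread came mainly from control replicate 3, at 0.47 against 0.23 and 0.22 in control replicates 1 and 2.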

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

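The tests of a stronger form of the same knockdown, and of other splits for the gene lists between the knockdowns, were chosen only after the results were seen, as were the ratios of falls to rises under other scalings. The criterion of the first was also widened once its value was known, since an earlier form had argued against a stronger knockdown although members moved both ways. The other tests below were fixed before their results were known.

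The direct comparison of the knockdowns gave 3473 genes with a different level, and 146 genes called in both knockdowns with opposite signs. Each of the other 9 ways to divide the 6 knockdown arrays into 3 and 3 gave 0 genes, but with 10 splits in all, of which 1 reached the real count, the share cannot fall under 0.05. The same holds for knockdown1 against control (4351 genes, highest other split 0, 1 of 10 as large) and knockdown2 against control (3608 genes, highest other split 0, 1 of 10 as large). For both knockdowns against control, 1 of 100 splits of the 9 arrays, the real one, gave as many as 4256 genes, and the highest other gave 2101. That share is under 0.05, so a random division of these arrays is an unlikely source of the count. For genes changed the same way in both knockdowns, 1 of 100 splits gave as many as 2048 and the highest other gave 1074, with the same reading. The arrays of a group may be technical repeats, and then neither test can exclude chance differences between single cultures. For gene lists, 5 of 100 splits gave as many as the real 17 shifted lists and the highest other gave 18, so chance cannot be excluded for that number. Between the knockdowns, 7 of 10 splits gave as many as the real 3 lists and the highest other gave 6, with too few splits for a share under 0.05.

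The test between the knockdowns found 3 lists with a different response, none of which passed with an estimated correlation (adjusted p = 0.235, 0.966 and 0.966 in the order given here). The mean difference of knockdown1 from knockdown2 was -1.88 for cell cycle and DNA replication, 0.72 for interferon-stimulated genes and -0.37 for glycolysis and hypoxia. For the cell cycle list, lower in knockdown1 in 40 of 40 genes, array scaling is argued against, since under 3 other scalings the list mean stayed between -1.79 and -1.76. RNA degradation would raise the 3 prime to 5 prime ratio in knockdown1, and the differences of -0.0075 for GAPDH and 0.0521 for ACTB argue against it. A stronger form of the same knockdown predicted lower hepatic genes in knockdown1. The 171 tested genes of 10 hepatic lists did not show this. Their median difference was 0.0499 (bootstrap SE 0.0478, and 0.17 with the values as deposited), with 26 genes lower and 25 higher in knockdown1. Their medians against control were -0.56 in knockdown1 and -0.63 in knockdown2. Strength alone would also not give opposite signs. The 146 genes with opposite signs, all different between the knockdowns, argue against it for those genes. For the cell cycle list a stronger knockdown cannot be told apart from a separate effect, since these values cover other genes. The bootstrap drew genes as if they were independent, so its SE leaves out their correlation and the spread between arrays. The probe sets of HNF4G differed in sign between the knockdowns and neither passed the threshold (-0.72, SE 0.28, and 0.28, SE 0.73), and HNF4A was not analysed here. The difference between knockdown1 and knockdown2 that the labels leave unnamed stays open as an untested biological or reagent difference.

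A second pattern is that 660 genes changed strongly in 1 knockdown only, by at least 2-fold with a difference between the knockdowns. For the 340 of these genes with a second probe set above the filter, a probe-specific artefact is argued against. Of those probe sets, 94.4% differed in the same direction (exact 95% interval 91.4% to 96.6%). The median ratio of the second to the first log2 difference was 0.82. The interval treats genes as independent, which they are not, and the remaining genes could not be checked in this way. Repression of unintended transcripts by the siRNAs of 1 preparation would give more falls than rises. Without the cell cycle list, 368 genes fell and 60 rose in knockdown1 only, a ratio of 6.13, and 116 fell and 78 rose in knockdown2 only, a ratio of 1.49. Leaving out that list took the falls in knockdown1 only from 406 to 368. Cell cycle genes outside the list stay in, such as KIFC1 (-3.67 in knockdown1 and -0.59 in knockdown2). The excess of falls in knockdown1 thus cannot separate such repression from the wider fall of cell cycle genes. Predicted was a ratio of at least 1.5 in both, which the second value misses, but under 3 other scalings the ratios were 2.93 to 3.66 in knockdown1 and 1.94 to 2.27 in knockdown2, so the outcome depends on the scaling and such repression stays open.

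The 16 genes with the largest differences between the knockdowns follow, from the test of that difference. Higher in knockdown1 were ANGPTL8 (4.63), CXCL8 (3.26), DKK4 (2.99), KRTAP3-1 (2.96), IFIT1 (2.96), NAGK (2.48), LYRM2 (2.42) and BMPR2 (2.39). Of these, DKK4 lay below control in both knockdowns. NAGK had a mean signal of 76.5 in knockdown2 against 431 in knockdown1 and 333 in control (n = 3 each). Of 4 other LYRM2 probe sets 3 had the same sign, and a dimmer LYRM2 probe set gave -0.13 (SE 0.46). Of 5 other BMPR2 probe sets, 1 gave 1.97 (SE 0.28, adjusted p = 2.50e-05) and 4 gave 0.03 to 0.32 with adjusted p of at least 0.377, so the BMPR2 difference rests on 2 of 6 probe sets. Lower in knockdown1 were ZNF367 (-4.04), CCNE2 (-3.47), RRM2 (-3.41), PRC1 (-3.29), KIFC1 (-3.08), TMEM158 (-3.01), ANKRD46 (-2.97) and CRYAA (-2.97). TMEM158 rose in knockdown2 (2.83, SE 0.60) and gave -0.19 (SE 0.60) in knockdown1 against control. Its signals in knockdown1 (5.16) and control (6.94) and that of CRYAA in knockdown1 (1.82) lay below the common median. The sizes and ranks of their differences therefore depend on the pseudocount.

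Outside the gene tests, 925 of 5086 probe sets with several gene names or none changed against control, 464 higher and 461 lower, 266 of them at least 2-fold. These carry signal that no gene count includes.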

How the results depend on the processing

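All alternatives except the values as deposited, added after seeing the data, were fixed before the data were examined. The fall of HNF4G kept its direction and its side of the threshold under every alternative that gave a value, and had none under the stricter filter. HNF4A gave no value under any. Called genes over both knockdowns numbered 2205 with the knockdown arrays pooled, where differences between the knockdowns count as spread. With all 29651 probe sets tested in place of genes they numbered 8059, and 8178, 6857 and 6535 for knockdown1, knockdown2 and the difference. At adjusted p under 0.01, 1351 genes changed the same way in both knockdowns. With an estimated correlation 0 lists were shifted over both knockdowns and 0 differed between them, while without the filter 6 differed, and the cause was not tested. Leaving out 1 array gave a range of -1.02 to -0.84 for HNF4G, 3303 to 4428 genes over both knockdowns, 3585 to 4613 for knockdown1, 2802 to 4037 for knockdown2, 2706 to 4171 between them, 1556 to 2274 changed the same way, 17 to 18 lists shifted and 2 to 5 lists different, the 5 without knockdown1 replicate 3. Without control replicate 3 the balance over both knockdowns turned to more higher genes (58.2%). The deviations gave little sign that the replicate numbers pair the arrays. Those of same-numbered arrays correlated at -0.02 to 0.13 (median 0.01), and 2 of 9 arrays lay closest to their own number. With the replicate block, however, the fits called more genes, 4905, 4996, 4265 and 4147 against 4256, 4351, 3608 and 3473 without it. A pairing by replicate number is therefore not excluded, and the main fit does not use one. Of 158 named-gene results, 136 kept their direction and call under the alternatives that gave a value (122 of 158 under the stricter filter, none at the 0.01 threshold or over all probe sets), and 49 of 3282 values fell short of the threshold and 0 reversed. These include CYP3A5, BNIP3, HMOX1, MCM5, TXNRD1, CLDN4 and NFKBIA when the knockdown arrays were pooled. Of 32 list results, 29 of 734 values lost and 19 gained a call and 0 called lists reversed. The oxidative phosphorylation list gained one under 10 settings. Dim signal limits HNF4G and other genes near the array median.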

Other observations

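Genes outside the fixed lists point to further biology. After the values were seen, EREG, which encodes the growth factor epiregulin, EGR3, DUSP5 and FOS were singled out for their rise, by 2.65 (SE 0.13), 2.98 (SE 0.17), 2.16 (SE 0.14) and 2.04 (SE 0.34) on the log2 scale. These genes are known to respond to growth factor signalling, and a candidate explanation is a wider rise of growth factor immediate-early and feedback genes. A list of 28 other such genes was written from general knowledge before their values were looked up. Of 25 tested, 20 rose and 0 fell over both knockdowns (camera p = 6.96e-13, and p = 0.0314 with an estimated correlation), among them IER2 (1.79, SE 0.13), EGR1 (1.70, SE 0.21) and LIF (1.46, SE 0.14), picked as examples after their values were seen. In knockdown1 15 rose and 1 fell, and in knockdown2 20 rose and 0 fell. The hypothesis was formed and tested on the same arrays, and the ways in which transfection or growth state could raise these genes were not tested.

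A second hypothesis came from the falls of ANKS4B, UNC93A, PDZK1, SLC5A9 and SLC7A9, with log2 fold changes of -3.47 (SE 0.51), -3.90 (SE 0.41), -2.66 (SE 0.22), -3.04 (SE 0.34) and -3.00 (SE 0.20), of which PDZK1, SLC5A9 and SLC7A9 were singled out after their values were seen. Proteins of this kind sit in or under the brush border of kidney and intestinal cells, so a wider fall of brush-border genes may be present. Of 15 tested genes of a further list of 27, 8 fell and 2 rose (camera p = 2.99e-05, and p = 0.0391 with an estimated correlation). VIL1 and ANPEP, which are among the 8, also belong to the fixed intestinal list, whose downward shift had already been seen. Without them, a test chosen only after that result was seen, 6 of 13 genes fell and 2 rose (camera p = 0.0014, and p = 0.053 with an estimated correlation). MEP1A fell by 2.55 (SE 0.26) and NHERF1 by 1.62 (SE 0.13), both picked as examples after their values were seen. HepG2 cells also form apical membranes that use such genes.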
